A study of Homo sapiens with 4 samples.

How the data were processed

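Total RNA from 4 sorted subpopulations of PC14, a human non-small-cell lung cancer cell line, was hybridised to 4 one-colour Affymetrix expression arrays with a biotin label, 1 array per subpopulation. Per the series' design text, cells were first sorted by fluorescence into E-cadherin-high and E-cadherin-low populations. Each was then sorted into CD133-high and CD133-low cells with a lentiviral reporter in which the P1 promoter of the CD133 gene drives green fluorescent protein.

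The values used are the deposited intensity per probe set on a linear scale. MAS5 is named per the submitters' processing notes, with a version not given in the sources used here. On each array the mean intensity after leaving out the top and bottom 2% of probe sets was 500.1, so the deposited intensities had been scaled within each array. The table held no detection calls, and scan dates or other batch labels are not given in the sources used here.

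The table held 54675 probe sets, of which 62 were controls. In the platform annotation, 41097 probe sets had 1 gene symbol and 1801 had several, and 11777 were unnamed here, controls included. The gene IDs of 41043 probe sets matched a RefSeq table (assembly GRCh38.p14), and 0 symbols differed from it. That table served only for gene names and for which genes neighbour each other. Probe sets with several symbols were not used for genes. This left 19775 genes, each represented by its probe set with the highest mean log2 signal over the 4 arrays.

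Without detection calls, the 50th percentile of the probe sets other than controls was taken as the floor of each array, and lower signals were set to it. A gene was measured when it lay above the floor on at least 1 array, which held for 14083 genes, and 10891 genes lay above it on all 4. The log2 ratio of each gene was taken within matched pairs of arrays that differed in 1 sorted marker. The E-cadherin comparison (low over high) had 1 pair in CD133-high cells and 1 in CD133-low cells. The CD133 comparison (high over low) had 1 pair in E-cadherin-high cells and 1 in E-cadherin-low cells. The 2 pairs of a comparison share no array. A gene was counted as higher or lower when the ratio was at least 2-fold in the same direction in both pairs. A gene at the floor on both arrays of a pair had a log2 ratio of 0, and where 1 array of a pair was at the floor the ratio is a lower bound, written "at least". With 1 array per subpopulation this rule includes no test, and the number of arrays limits the precision. The additive fit named below takes the effects of the 2 markers as independent of each other, and its calls are given as counts.

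These choices, the 26 gene lists and the rule for the genes named were made before the data were examined. Named are the genes of the sorted markers, the 12 genes at the top of each direction of each comparison by the smaller of the 2 absolute log2 ratios, and up to 4 members of each list among those counted. Also named are the 10 genes with CD133 ratios in opposite directions that rank highest by the smaller of the 2 absolute log2 ratios. Genes named outside that rule are marked as chosen after the values were seen. For 25 lists, the median log2 ratio of the measured members was placed among 10000 random lists of the same size matched on mean signal in 20 bins. This percentile describes these arrays and is not a test of the conditions.

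The procedure was tested on simulated data. In simulated arrays with planted changes, 14622 genes were above the floor. Changes were planted only in genes whose mean log2 signal was at or above the mean floor, so recovery in dimmer genes was not measured. For the E-cadherin comparison the counting rule recovered 80% of 25 genes planted at a log2 change of 1.5 and 96% of 25 planted at 2. For the CD133 comparison it recovered 64% and 80%. In 20 simulated sets of unchanged arrays, with noise drawn from the disagreement between pairs, at most 53 genes met the E-cadherin rule and at most 56 the CD133 rule. Of 200 random lists of 30 simulated genes, 3% fell outside the percentiles 2.5 to 97.5. The simulated noise was drawn gene by gene, so lists whose members vary together were not covered.

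Shifted runs of neighbouring genes were sought in 10871 genes in RefSeq order with medians over windows of 40 genes, against the highest window median in 100 shuffled orders. This search was added after the data were seen.

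Alternatives were quantile normalization, equal array medians, no floor, floors at the 25th and 65th percentiles, thresholds of 1.5-fold and 3-fold, the mean over a gene's probe sets, leaving out probe sets whose IDs mark them as shared between transcripts or genes, and an additive limma fit. That fit had 1 residual degree of freedom and a Benjamini-Hochberg threshold of 0.05. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.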

Results

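Gene expression was measured in 4 subpopulations of PC14 lung cancer cells sorted by the adhesion protein E-cadherin and by CD133, a surface protein used as a marker of stem-like cancer cells. The design crosses the 2 markers, so that the genes that go with the epithelial or mesenchymal state can be set beside those that go with CD133. Each subpopulation was represented by 1 array, and none of the differences below has a replicate check. Between 12309 and 12460 of the 19775 named genes lay above the floor of an array, and the floors were signals of 53.7 to 60.3. The 27 probe sets for bacterial RNAs other than the spiked ones lay below the floor on all arrays, with highest signals of 34.2 to 54.3. The 3' over 5' signal ratio of actin was 1.53 to 1.78 and that of GAPDH 0.898 to 1.02. The array of E-cadherin-low CD133-high cells had the highest value of both. The 5' probe set for 18S ribosomal RNA read 13204 and 14297 on the E-cadherin-high arrays and 8619 and 7226 on the E-cadherin-low arrays.

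The gene for E-cadherin, CDH1, followed the sort by its brighter probe set, which read 5548 in E-cadherin-high and 347.0 in E-cadherin-low cells among CD133-high cells, and 3546 and 527.8 among CD133-low cells. These are log2 ratios of -4.00 and -2.75. Its other probe set lay near or below the floor on all arrays and gave no ratio in the same direction. The gene for CD133, PROM1, gave no measure of its sort. Its only named probe set read 12.1 and 10.3 in the CD133-high and 29.7 and 4.8 in the CD133-low subpopulations, below the floor on all 4 arrays. CD133 status therefore rests here on the reporter sort alone.

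E-cadherin-low cells had lower signals of genes for epithelial adhesion and higher signals of a set of genes that includes an E-cadherin repressor. ZEB1, the transcription factor that represses CDH1, was 7.74-fold higher in CD133-high and 16.3-fold higher in CD133-low cells. MAP2, a microtubule-binding protein of neurons, was 15.9-fold and 23.6-fold higher, and POSTN, a secreted matrix protein, 7.74-fold and 13.3-fold. In the other direction, MAL2, a protein of apical membrane traffic, read 10870 in E-cadherin-high and 282.7 in E-cadherin-low cells among CD133-high cells, and 8772 and 664.3 among CD133-low cells, log2 ratios of -5.26 and -3.72. DSP, the desmosomal plaque protein desmoplakin, had log2 ratios of -2.86 and -3.54, and DSG2, a desmosomal cadherin, -1.86 and -2.82.

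The rest of the genes at the top of this comparison came from several groups. Higher in E-cadherin-low cells were the scaffold protein AKAP12 (log2 3.15 and 3.13 in CD133-high and CD133-low cells), the membrane protein EMP1 (2.94 and 3.27), the fibrillar collagen COL11A1 (2.74 and 2.80), the ligand EFNB2 (2.44 and 2.30) and the cadherin CDH10 (1.93 and 2.27). DKK1, a secreted Wnt inhibitor, was higher by 2.61 and 1.85. DOCK10, the Wnt agonist RSPO3 and AMIGO2 were at the floor in both E-cadherin-high subpopulations and were at least 6.59-fold, 5.43-fold and 4.70-fold higher in either pair. Lower in E-cadherin-low cells were the receptor kinase EPHA1 (by at least 6.27-fold in either pair), TC2N (-2.54 and -2.78), ADGRL2 (-2.38 and -3.06), the R-spondin receptor LGR4 (-2.30 and -2.43), LMO7 (-2.23 and -2.76), PRSS12 (-2.49 and -1.94), ATXN1-AS1 (-1.72 and -2.02) and the complement component C3, with -1.66 and a bound of -3.17.

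In all, 67 genes were at least 2-fold higher and 76 at least 2-fold lower in both pairs. Independent pairs would give 14.1 and 10.2 if each gene were equally likely to pass. Dimmer genes had a wider spread, and simulated unchanged arrays gave up to 31 and 28. In simulated unchanged arrays the highest count over both directions was 53, against 143 observed. Across the 14083 measured genes, which are not independent replicates, the ratios of the 2 pairs had a Pearson r of 0.152 and a Spearman rho of 0.0885. The additive limma fit called 9 genes higher and 12 lower, all of them among the counted genes.

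Of 40 measured genes for epithelial junctions and adhesion, 12 were lower in both pairs, 0 were higher and 28 were neither. The 12 included CDH1, MAL2, DSP and the desmosomal cadherin DSC2 (-1.57 in CD133-low cells and, as a bound, -3.28 in CD133-high cells). The median log2 ratio of the list was -0.61 and -0.91 in the 2 pairs, and its mean over pairs lay below all 10000 random lists. The list also holds genes without a count, named here after their values were seen: EPCAM, an epithelial adhesion molecule, had ratios of -0.91 and -1.51, and the tight junction gene TJP1 had 0.23 and 0.35. Without the probe sets marked as shared, the median over both pairs went from -0.80 to -0.30.

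Of 38 measured mesenchymal genes, 3 were higher in both pairs and 1 was lower. ZEB1, POSTN and the receptor kinase AXL (2.49 and, as a bound, 1.40) were higher, and CAV1, the main protein of caveolae, was lower with -1.03 and -2.19. The list's median was 0.19 in CD133-high and -0.02 in CD133-low cells, and over both it was 0.17, at percentile 99.5. Also named after their values were seen are VIM, CD44, ZEB2, SNAI2 and TWIST1. VIM, the intermediate filament vimentin, had ratios of 0.70 and 2.89. CD44, ZEB2 and SNAI2 lay below the floor on all arrays, and TWIST1 read 11888 to 20662 without following the sort (0.14 and -0.80). Among 10 measured transcription factors of the epithelial to mesenchymal transition, 1 was counted, ZEB1. The median of that list was 0.12.

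Other lists gave fewer members. In E-cadherin-low cells, genes of antigen presentation by MHC had a median of -0.26 over both pairs (percentile 0.42), with 0 of 17 counted, and all of it came from CD133-low cells (-0.68, against -0.00 in CD133-high cells). Genes of lipid and cholesterol synthesis had a median of -0.20 (percentile 0.41), but 0.08 in CD133-high and -0.38 in CD133-low cells, with MVD lower (-1.04 and, as a bound, -1.14). Cell cycle genes had a median of -0.11 (percentile 1.38), but -0.28 in CD133-high and 0.13 in CD133-low cells, with 0 of 50 counted. The 48 ribosomal protein genes had a median of -0.23, below all 10000 random lists, but of -0.03 after quantile normalization. Of 25 lists, 5 lay in the lowest 2.5% of random lists and 1 in the highest 2.5%. By chance 5% of the lists would lie in either if list members varied independently. Members of a list can vary together and some lists share genes, so more than 5% may lie there without an effect of the sort. In the remaining 19 lists the median was -0.21 to 0.15. Besides genes named above, counted members there were the cystine transporter SLC7A11 (-1.41 and -1.53), the growth factor HBEGF (-1.25 and -1.54), the integrin ITGB4 (-1.11 and -1.60), the lung lineage factor GATA6 (-1.12 and -1.74), the Wnt receptor FZD1 (1.08 and 1.30) and GAS1 (4.06-fold and at least 2.82-fold higher). Other probe sets above the floor for ITGB4, GATA6, FZD1 and GAS1 did not go the same way. The 19 lists were keratins, transition factors, stem-cell genes, drug transport, TGF-beta and BMP, Wnt, Notch, Hedgehog, receptor kinases, integrins, matrix proteases, cytokines, interferon response, hypoxia and glycolysis, lung lineage, stress genes, markers of other cell types, markers of other lineages and housekeeping genes.

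**Figure D1:**
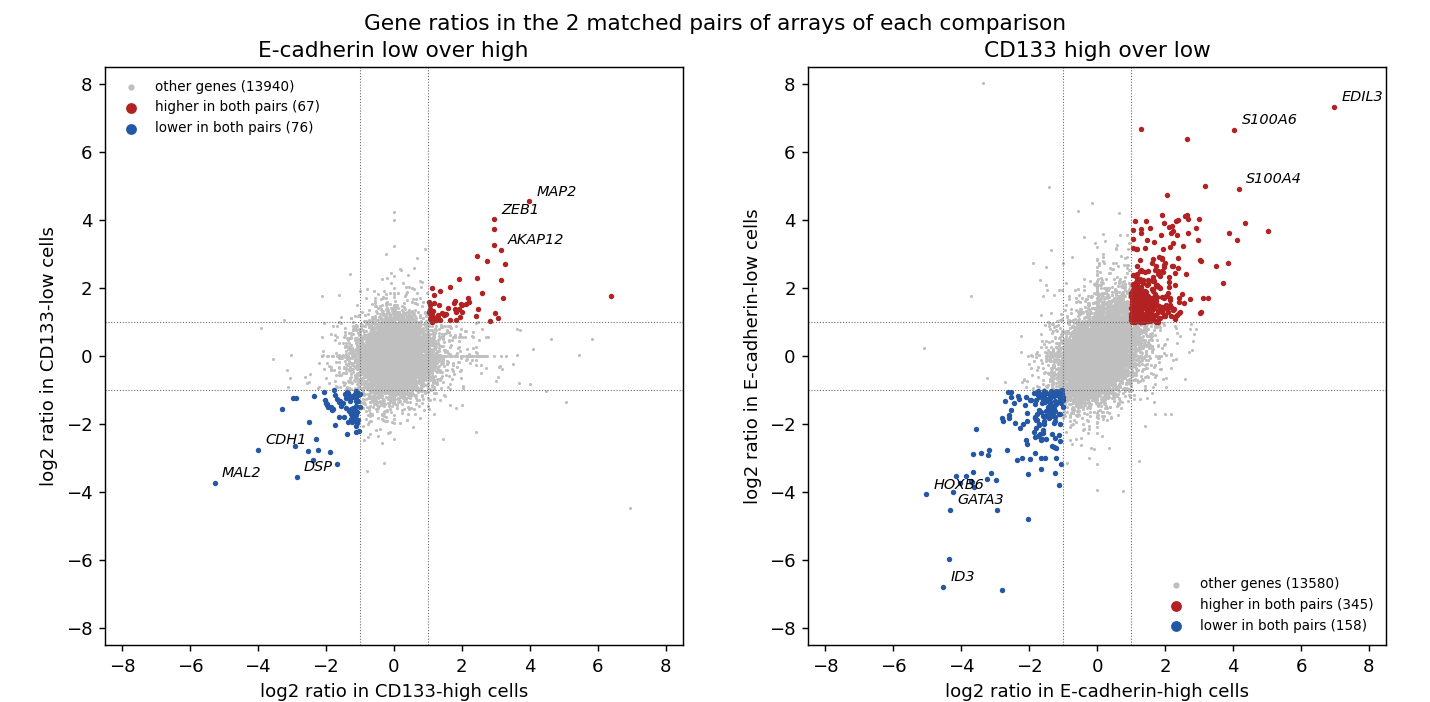
Log2 ratio of each measured gene in the 2 matched pairs of arrays, for E-cadherin low over high (left) and CD133 high over low (right). Each point is a gene, dotted lines mark 2-fold, and coloured points passed 2-fold in the same direction in both pairs, 67 higher and 76 lower on the left and 345 and 158 on the right.

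CD133-high cells differed from CD133-low cells in more genes than E-cadherin-low cells did from E-cadherin-high cells. EDIL3, a secreted integrin ligand, read 7185 and 9271 in the CD133-high subpopulations and lay below the floor in both CD133-low subpopulations, a difference of at least 125-fold in E-cadherin-high and at least 163-fold in E-cadherin-low cells. The calcium-binding protein S100A4 was 17.9-fold and 30.5-fold higher, the related S100A6 at least 16.4-fold and at least 102-fold, and the galectin LGALS1 8.98-fold and 32.1-fold. ID3, an inhibitor of basic helix-loop-helix transcription factors induced by BMP signals, went the other way, with 771.3 and 180.8 in CD133-high against 17878 and 19862 in CD133-low cells. GATA3, a lineage transcription factor, had log2 ratios of -4.32 and -4.52.

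Other genes at the top of the CD133-high side were the fibrillin FBN2 (log2 3.87 and 3.62 in E-cadherin-high and E-cadherin-low cells), the membrane protein MYOF (2.99 and 4.04), PNMA2 (4.12 and 3.43), CAND2 (3.03 and 2.83) and MYEF2 (2.90 and 3.77). The nuclear protein TOX had 5.02 and a bound of 3.69, and the muscle protein KLHL41 bounds of 4.35 and 3.92. PRDM16, a transcriptional regulator, had 2.97 and a bound of 3.41, while its other probe set above the floor went the other way. Lower in CD133-high cells were the channel gene MCOLN3 (-4.37 and, as a bound, -5.97), SYDE2 (-4.24 and, as a bound, -4.00) and the adaptor SKAP2 (-3.63 and -3.84).

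The remaining genes at the top of the lower side belonged to HOX clusters, whose members set positional identity in development. HOXB6 had log2 ratios of -5.03 and -4.06, HOXB3 -4.03 and -3.72, HOXB7 -4.14 and -3.53, HOXB5 -3.85 and -3.52 and HOXB8 -3.66 and -3.42. HOXA2 and the antisense gene HOXB-AS3 were at the floor in both CD133-high subpopulations and were lower by at least 12.8-fold and 12.7-fold in either pair. A list of all HOX genes, made after these values were seen, had 25 measured members, of which 14 were lower, 0 higher and 11 neither. Of the 14, 8 were HOXB genes, and HOXD10 (-2.61 and -1.74) and HOXD13 (-1.50 and -1.60) were among the others. HOXC6, at 4315 to 9117, had -0.38 and -0.58. Without the probe sets marked as shared, the mean ratio of HOXB6 was -0.26 and that of HOXB8 -1.11. The probe set of HOXB3 was not marked as shared from the start, so its mean ratio of -3.87 could not change. The HOX median was -1.50 and -1.61 in the 2 pairs.

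In all, 345 genes were at least 2-fold higher and 158 at least 2-fold lower in CD133-high cells in both pairs. Independent pairs with genes equally likely to pass would give 57.6 and 19.5, and simulated unchanged arrays gave up to 33 and 30. The highest count over both directions in simulated unchanged arrays was 56, against 503 observed. The ratios of the 2 pairs had a Pearson r of 0.490 and a Spearman rho of 0.404 across genes. The additive limma fit called 185 genes higher and 104 lower, of which 167 and 96 were among the counted genes. When the 4 arrays were split by each marker, 353 genes separated the CD133-high from the CD133-low arrays by at least 2-fold, 66 the E-cadherin arrays and 15 the diagonal pairing of the arrays. In simulated unchanged arrays these splits reached up to 29, 32 and 28 genes.

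Genes of lipid and cholesterol synthesis were higher in CD133-high cells, with 6 of 22 measured members counted and 0 lower. HMGCS1, which makes the substrate of HMG-CoA reductase, was higher by log2 1.78 and 2.51, the sterol oxidase MSMO1 by 1.47 and 2.10, the squalene epoxidase SQLE by 1.39 and 1.79, and the sterol sensor INSIG1 by 1.02 and 1.90. The median of the list was 0.75 and 0.82 in the 2 pairs, and over both it lay above all 10000 random lists. Genes of the TGF-beta and BMP pathway had a median of -0.29 over both pairs (percentile 0.11), from -0.17 and -0.29 in each, and of -0.15 with the floor at the 65th percentile, with 5 of 26 lower. ID2 had log2 ratios of -2.94 and -4.52, the BMP inhibitor SMAD6 -2.07 and, as a bound, -2.59, and the pseudoreceptor BAMBI -1.53 and -3.01.

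Some genes tied to matrix and antigen presentation were also higher in CD133-high cells, with list medians shifted mainly among E-cadherin-low cells. Matrix proteases and inhibitors had a median of 0.52 over both pairs (percentile 99.98; 0.07 in E-cadherin-high and 0.69 in E-cadherin-low cells), with 3 of 21 higher. These were the inhibitor TIMP2 (1.17 and 2.30), the protease ADAM9 (1.02 and 1.05) and the plasminogen activator PLAT, with bounds of 1.07 and 3.44. The median E-cadherin ratio of this list was 0.18 in CD133-high and -0.15 in CD133-low cells, so both E-cadherin-low arrays may enter the 0.69. MMP1 and TIMP1 were named after their values were seen. On the array of E-cadherin-low CD133-high cells they read 367.4 and 271.6, against at most 60.1 and 67.4 elsewhere. Such single members move a median of 21 genes little. MHC genes had a median of 0.51 (percentile 99.97), from 0.17 and 0.79 in the 2 pairs. The larger value shares the array of E-cadherin-low CD133-low cells with the lower MHC median of the E-cadherin comparison, so low signals on that 1 array enter both. Counted as higher were 2 of 17, HLA-DPA1 (2.01-fold and 3.43-fold) and CD74 (2.84-fold and at least 3.44-fold). Mesenchymal genes had a median of 0.28 (percentile 99.94), near equal in the 2 pairs (0.30 and 0.33) but 0.14 without the probe sets marked as shared and 0.15 as the mean over probe sets, and S100A4, AXL (3.32 in E-cadherin-low cells and a bound of 2.24), the proteoglycan LUM (1.46 and 3.41) and DCN were higher while CCN1 was lower (-2.80 and -1.83). Drug transport and detoxification genes had a median of 0.24 (percentile 98.9), from 0.04 and 0.35, with CYP1B1 (1.88 and 3.56) and GSTM3 (2.14 and 3.22) higher of 24. That median was -0.02 without the probe sets marked as shared, where GSTM3 was at -0.02 as well.

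Of 25 measured stem-cell and tumour-initiating cell genes, 1 was higher in CD133-high cells, LGR4 (1.86 and 1.99), and 2 were lower, ID2 and ID3, with a list median of -0.10 (percentile 21.6). LGR4 was thus higher with CD133 and lower in E-cadherin-low cells. Among epithelial genes 1 of 40 was counted, MUC1 (1.09 and 1.98), with a list median of 0.09. Other counted members of lists came in small numbers, among them the following. SOX9 (2.38-fold and 3.58-fold), VEGFC (2.005-fold and 2.65-fold), the Wnt inhibitor DKK3 (2.30 and 2.45), the Notch ligand DLL1 (2.04 and 1.52), MAML3 (1.10 and 1.12), IFI6 (1.30 and 1.11), USP18 (1.02 and 1.52), ALDOC (1.36 and 1.69), BNIP3L (1.18 and 1.80) and DUSP6 (2.28 and 1.10) were higher. DKK1 (-1.85 and -1.09), FZD1 (-1.28 and -1.50), HBEGF (-3.20 and -2.91), MET (-1.16 and -1.06), TNFSF10 (-2.64 and -1.05), ADM (-2.37 and -3.05) and HK2 (-1.73 and -1.15) were lower. NOTCH4 (1.07), BOC, ISG20, FOSL1 and CCND2 (2.65) were higher with a bound in at least 1 pair. In the list of markers of other cell types, LUM, the proteoglycan DCN (1.17 and, as a bound, 2.65) and the leukocyte protein PTPRC (1.85 and 1.13) were higher of 14, with a list median of -0.06.

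Of the 25 lists, 5 lay in the highest 2.5% of random lists and 1 in the lowest 2.5% in the CD133 comparison. The other 19 had medians of -0.22 to 0.23. These were the epithelial, keratin, transition factor, stem-cell, Wnt, Notch, Hedgehog, receptor kinase, integrin, cytokine, interferon, hypoxia, cell cycle, lung lineage, stress, other cell type, other lineage, housekeeping and ribosomal lists.

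**Figure D2:**
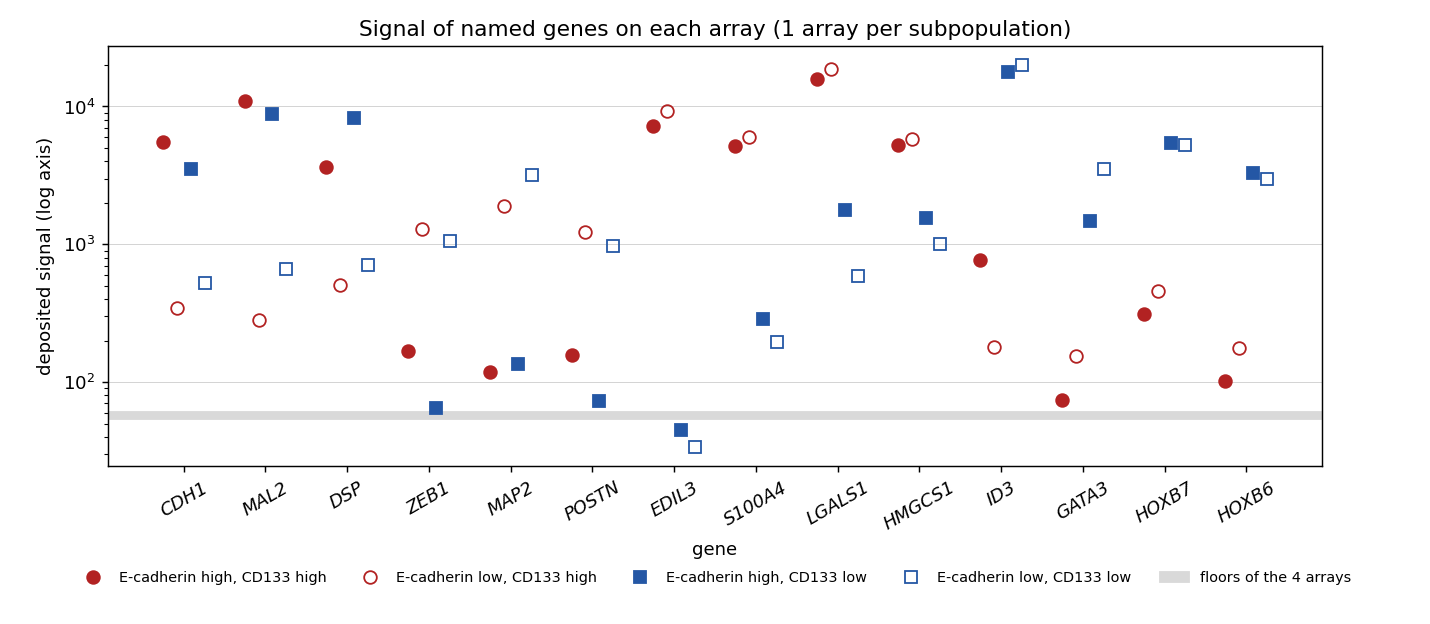
Deposited signal of named genes on each of the 4 arrays, on a log axis. Each symbol is 1 array, circles are CD133-high, squares CD133-low, filled symbols E-cadherin-high and open symbols E-cadherin-low, and the grey band spans the floors of the arrays, from 53.7 to 60.3.

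Whether the CD133 difference itself depends on the E-cadherin state could be described but not tested. In 32 genes the CD133 ratio was at least 2-fold in opposite directions in the 2 E-cadherin states. That is fewer than the 67.3 of independent pairs with genes equally likely to pass and the 58 reached in simulated unchanged arrays. The simulated noise was itself drawn from the disagreement between pairs, so the count neither shows nor excludes such a dependence. TFPI2, a protease inhibitor, had the largest such difference of the 10 named, with a log2 CD133 ratio of -3.37 in E-cadherin-high cells and a bound of 8.04 in E-cadherin-low cells. The immediate early transcription factor EGR1 had -1.59 and 1.78, and the scavenger receptor OLR1 had -3.73 and 1.77.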

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

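The results below are differences between the CD133 ratios of the 2 E-cadherin states, or between the E-cadherin ratios of the 2 CD133 states, in which the pairs went in opposite directions. None of these differences was tested, because each subpopulation had 1 array, and array noise was not separated from a real dependence of one marker on the other. There were 32 genes of this kind in the CD133 comparison, where simulated unchanged arrays gave up to 58, and 33 in the E-cadherin comparison. Independent pairs with genes equally likely to pass would give 67.3 and 24.8. The simulated noise was drawn from the same disagreement between pairs, so it cannot decide on these genes.

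For single genes, the value is the log2 CD133 ratio in E-cadherin-low minus that in E-cadherin-high cells. It was 11.40 for TFPI2, 5.50 for OLR1, 4.64 for the endopeptidase MME, 4.13 for TMEM52B, 3.91 for EEF2KMT, 3.61 for SKIDA1 and 3.37 for EGR1, which were higher with CD133 in E-cadherin-low and lower in E-cadherin-high cells. For TFPI2, MME, TMEM52B, EEF2KMT and SKIDA1 at least 1 array was at the floor, so these values are bounds. It was -3.87 for the glycogen phosphorylase PYGB, again a bound, -3.70 for FBXO43 and -3.40 for the stress kinase MAP2K6, which went the other way. The highest signal of TFPI2, MME, OLR1, TMEM52B, SKIDA1 and EGR1 was on the array of E-cadherin-low CD133-high cells, with 14974 for TFPI2 and 4531.5 for MME.

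The list members FOS, ATF3, PCNA and KRT7 were named after their values were seen. Among the lists, 5 had medians in opposite tails of the random lists in the 2 pairs. Stress and immediate early genes had a median E-cadherin ratio of 0.55 in CD133-high and -0.44 in CD133-low cells, a difference of 0.99, with FOS at 1.17 and -0.91 and ATF3 at 1.24 and -1.09. The 0.55 and the median CD133 ratio of 0.55 in E-cadherin-low cells share the array of E-cadherin-low CD133-high cells, which had the highest 3' over 5' ratios and the most genes standing apart, while the -0.44 does not involve that array. Receptor kinases and their ligands differed by 0.65 (0.42 and -0.23) and cytokines by 0.49 (0.28 and -0.21). Cell cycle genes differed by -0.40 (-0.28 and 0.13), with PCNA at -0.98 and 0.89. The 5 measured keratins had a median CD133 ratio of 0.54 in E-cadherin-low and -0.57 in E-cadherin-high cells, a difference of 1.11, with KRT7 at 0.85 and -1.26.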

How the results depend on the processing

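Leaving out arrays in turn, keeping genes above the floor on all 4 arrays and leaving out runs of shifted neighbouring genes were alternatives chosen after the data were seen. Values below are in the order E-cadherin-low higher and lower (67 and 76), CD133-high higher and lower (345 and 158), opposite directions (32) and diagonal split (15). These counts were within 1.5 times under quantile normalization and equal array medians, where 482 and 472 CD133 genes were counted against 503, with 465 and 456 the same genes, and also without the probe sets marked as shared. The 4 higher and lower counts were so without the shifted runs as well. With the floor at the 25th percentile the counts were 335, 241, 626, 362, 392 and 259. With no floor the E-cadherin counts were 128 and 127, opposite 106 and diagonal 73, and at the 65th percentile E-cadherin-low higher was 34, CD133-high higher 222, opposite 10 and diagonal 5. At 1.5-fold they were 250, 258, 933, 554, 224 and 112, and at 3-fold 18, 13, 95, 61, 8 and 3, as the threshold itself sets. The mean over probe sets gave 40, 40, 203, 92, 18 and 8. That mean includes probe sets at the floor, whose ratios are near 0 and pull the gene's ratio towards 0. How much this alone lowered the counts was not measured. The additive limma fit gave 9, 12, 185 and 104. Without 1 array, the rule rests on the single pair left, so the counts were higher by construction, at 371 to 536, 356 to 404, 710 to 1142 and 456 to 601. Restricting to genes above the floor on all 4 arrays gave 44 genes higher in E-cadherin-low cells. In each of these settings with both directions counted, CD133 had more genes than E-cadherin. Without the probe sets marked as shared, the mean log2 ratio changed sign for GAS1 in the E-cadherin comparison (-0.18) and for PRDM16 (-0.70) and GSTM3 (-0.02) in the CD133 comparison. The CD133 median of the drug transport list changed sign there (-0.02) and with the floor at the 25th percentile (-0.01), and the cause was not tested. Of the values of named genes under the alternatives, 616 stayed within 1 standard deviation of the 2 pairs, 154 moved beyond it and 3 changed sign. For list medians, 260 stayed within that bound and 102 moved beyond it. The 2 set apart as changes of sign were those of the drug transport list above. Some of the medians that moved also changed sign. The E-cadherin median of the integrins went from 0.12 to -0.26 with no floor and to -0.41 with the floor at the 65th percentile. The 0.12 is a median over each gene's mean of the 2 pairs, and within the pairs the medians were -0.08 and -0.09. The E-cadherin median of the lung lineage list went from 0.09, with 0.00 in each pair, to -0.37 with the floor at the 65th percentile. The spread per array was estimated without the floor from the disagreement between pairs. It was 0.88 log2 in the 4694 dimmest genes and 0.27 in the 4695 brightest. These values stand for array noise only if nothing else makes the pairs differ.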

Other observations

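The noise, founder, DNA and gene order tests below were chosen after the results were seen. The tests of scaling, of shifted runs as the source of CD133 genes and of HOX paralogs had their bounds written before those tests were run. The genes in the next paragraph were chosen after their values were seen.

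Single arrays stood apart in some genes. On the array of E-cadherin-low CD133-high cells, 56 genes were at least 4-fold above each other array and 8 at least 4-fold below. SPP1, the secreted phosphoprotein osteopontin, read 18750 there and 175.7 to 428.2 elsewhere, the cyclin CCND2 4749.5 against at most 418.4, and the kinase SGK1 2987.5 against 175.5 to 264.1. FOXA1, an endodermal transcription factor, read 226.4 there and 1798 to 2381 elsewhere. The other arrays had 2 to 7 genes above and 2 to 12 below. SOX2, a pluripotency factor, read 88.3 in E-cadherin-high CD133-high cells and 3021 to 5006 elsewhere. VIM read 1740 in E-cadherin-high CD133-low cells and 12448 to 20200 elsewhere. FABP7, a neural fatty acid-binding protein, read 7086 in E-cadherin-low CD133-low cells and 377.3 or less elsewhere, and MAGEC2, a cancer-testis antigen, 538.8 against signals below the floor.

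The CD133 comparison counted 503 genes and the E-cadherin comparison 143. Noise that is independent between arrays is argued against by 20 simulated sets of unchanged arrays, which gave at most 56 CD133 genes. A handling difference shared by the arrays of the same CD133 state was not simulated. After quantile normalization, which removes scaling differences, 482 genes were counted against 140 for E-cadherin. Long runs of shifted neighbouring genes hold 5.85% of the 376 CD133 genes above the floor on all 4 arrays. Of all ordered genes they hold 2.67%. That search took medians over wide windows, so shorter blocks may escape it. In gene order, 19 neighbouring pairs were both lower, against a mean of 1.75 and at most 7 in 1000 shuffled orders. Another 25 pairs were both higher, against a mean of 8.43 and at most 20. Neighbouring genes therefore share part of the count, and the size of that part was not measured. The HOXB genes, of which 8 were lower, lie in 1 cluster and can form such pairs. The 19 lower pairs may therefore in part repeat the HOX result. A difference between founder cells of the sorted populations, unrelated to CD133, remains open, because with 1 array per subpopulation no second sort of the same state is there to compare. Higher CD133 promoter activity, a founder difference and a batch difference may each give such a count. PROM1 below the floor leaves the CD133 state itself unmeasured. Without batch labels it is not known whether CD133-high and CD133-low arrays were handled apart.

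In CD133-high cells, 14 of 25 measured HOX genes were lower in both pairs and 11 were not counted. Loss of DNA around the HOXB cluster would lower its neighbours too, yet the 10 measured genes on each side, from KPNB1 to FAM117A, had a median log2 ratio of -0.06 (quartiles -0.43 and 0.26) against -3.61 for the 8 HOXB genes above the floor on all 4 arrays. This does not exclude a loss confined to the cluster, but 6 HOX genes of other clusters were also lower. The HOX median was -1.37 in probe sets not marked as shared. Many lower HOX genes, such as HOXB2 (-3.13) and HOXB4 (-3.43), had such a probe set from the start, so this median could move little. The lower ratios of those genes do not rest on probe sets marked as shared. The ratios of HOXB6 and HOXB8 shrank when such probe sets were left out, that of HOXB6 to -0.26. Cross-hybridisation between HOX paralogs therefore stays open for these genes. No biological explanation was tested, and a difference between the CD133 states or between their founder cells stays open.

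On the array of E-cadherin-low CD133-high cells, a run of 121 neighbouring genes from ZCCHC3 to CBFA2T2 was lower, the longest lower run among the 5 runs found in this ratio, while the other ratios had 1, 1 and 4. Its median log2 E-cadherin ratio was -0.70 in CD133-high cells, with 82.6% of the genes lower, and -0.13 in CD133-low cells. The highest window median in the run was 1.07 in size, against at most 0.41 over 100 shuffled gene orders, which argues against a chance order. In the other pair that holds this array, the CD133 ratio among E-cadherin-low cells, the median was -0.43, but the run was found on that array, so this value follows from the choice and supports no cause. Fewer DNA copies of the segment in these cells and a shared change in transcription of the region both stay open, since no DNA was measured.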
